A study of Arabidopsis thaliana with 16 samples.

How the data were processed

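RNA of sorted root cells of Arabidopsis thaliana was measured on 16 Affymetrix arrays of 5 populations, 1 hybridization per sample. Cells of the epidermis with lateral root cap gave 4 arrays, and cells of the columella, the cortex, the endodermis with quiescent center, and the stele gave 3 arrays each. The deposited intensity values are MAS5 signals on a linear scale, calculated by the authors from the scanned arrays and scaled per array, per the submitters' processing notes. The version of MAS5 was not given. The trimmed means of the 16 columns (2% trimmed) differed by less than the 5% set as a limit before the data were examined, so the deposited scaling was kept. The table held 22810 probe sets, of which 64 are controls and were used only as quality values. No detection calls, scan dates or batch labels were available, and 0 of 120 pairs of columns were identical. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples.

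Signals entered as log2(signal + 10.21), the pseudocount being the 20th percentile of the table. Folds are therefore on that scale and are smaller than ratios of the signals where signals are low. Probe sets with at least 3 arrays at or above 38.05, the 40th percentile, were tested, which left 16221. A model with a mean for each population was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend, 11 residual degrees of freedom). Tests were 2-sided, and p-values were adjusted by Benjamini and Hochberg over the probe sets of each contrast at a threshold of 0.05. The contrasts were the moderated F test over all populations, each population minus the mean of the other 4, all pairs of populations, and a slope over epidermis, cortex, endodermis and stele with weights -3, -1, 1 and 3. A probe set was called enriched in a population when it was higher there than in each of the other 4 by the pairwise tests. Spreads beside signals are SDs over arrays, and SE is that of the fitted difference. The signal above background limits what arrays can show, and the number of arrays limits the precision. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

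Gene names came from an annotation table of the array that names 1 gene for 13513 probe sets, several for 503 and none for 8794. Of the tested probe sets 6890 had no gene, and 1231 had a symbol other than a locus tag. The rule for named genes was set before the data were examined. It took, per population, the 10 enriched probe sets with 1 gene symbol and the largest difference to the next population, every array lying above every other array. It also took the 4 largest decreases by the same rule, the 5 steepest slopes each way, the genes of the reporters and every member of the gene lists. That a symbol has to differ from the locus tag was decided after the annotation was seen. A gene with several probe sets is given by the one with the highest mean. That applied to BTSL1, whose 2 probe sets correlated at 0.83 over the arrays. F6'H1, BTSL1, BTSL2, IMA1, MTP2, COSY, PASPA3, RCPG, SGN1, GH3.5, ZAT10, HSP17.6C and HSP22.0 are names given to loci that the annotation lists without a symbol or under another one.

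Before the data were examined, 32 gene lists with 455 loci were written from general knowledge, on iron, metabolism, hormones, stress, the cell cycle and markers of cell types. The annotation named 66 of these loci and 57 were tested. A list needed 4 tested members, which left the lists of iron regulators, starch, cortex markers and auxin response, tested in 5 populations each (20 pairs, adjusted together). The test was camera with a preset correlation of 0.01, and none of its 6 calls was kept with an estimated correlation. Members of 21 more lists are given as single genes. The lists of aliphatic glucosinolates, aquaporins, auxin transport, ethylene, iron storage, internal iron transport and nutrient uptake had no tested member. The genes of 3 of the 4 reporters, and genes such as IRT1, FRO2 and FIT, were not named by the annotation and were left out. After the data were seen, 30 gene families sharing the letters of a symbol, with 6 or more members, and the genes of the plastid were also tested.

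Alternatives were quantile normalization, other pseudocounts, other filters, eBayes without a trend, array weights, the replicate number as a block, fry, the mean over the probe sets of a gene, and leaving out each array. On simulated data of the same design and spread, with 200 probe sets changed per comparison, 50 to 66% of changes of 2-fold were recovered for a population against the other 4, and 94 to 98% of 4-fold changes. For enriched probe sets these were 8 to 28% and 76 to 88%. In the simulation 15021 of 16221 probe sets were unchanged and no array lay apart from its group, while most probe sets differed in the data. The adjusted threshold was therefore stricter in the simulation, so these percentages do not measure recovery in the data. Each rests on at most 50 probe sets.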

Results

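The series asked how gene expression under iron deficiency varies with cell identity across the root of Arabidopsis thaliana. Transcript levels were measured on 16 Affymetrix arrays, each hybridised with RNA from 1 population of root cells. Seedlings aged 6 days were moved for 24 h to medium without iron that held 0.3 mM ferrozine, a chelator that binds ferrous iron. Roots were then digested to protoplasts, which are cells without walls, and cells carrying green fluorescent protein were collected by fluorescence-activated sorting. A different reporter line marked each population: epidermis with lateral root cap (n = 4 arrays), columella (n = 3), cortex (n = 3), endodermis with quiescent center (n = 3) and stele, the central cylinder that holds the vascular tissue (n = 3). They are called epidermis, columella, cortex, endodermis and stele from here on. Every array came from iron-deficient roots. Arrays of iron-sufficient roots were not analysed here, so each value below is a level under iron deficiency and none is a response to it.

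All 16 arrays had the same trimmed mean signal, and their median signals ran from 50.0 to 81.1. The number of arrays limits the precision. Arrays of 1 population correlated with each other at r = 0.894 to 0.981 across 16221 probe sets, and arrays of different populations at 0.639 to 0.878. Genes are not independent replicates, so these values only describe the arrays. The first component held 36.6% of the variance and placed epidermis and columella apart from cortex, endodermis and stele. The second component held 25.7%. Epidermis replicate 4 was the array that lay farthest from its own group. Its correlation with epidermis replicates 1 to 3 was 0.894 to 0.938, against 0.970 to 0.981 among those 3, and its correlation with the cortex arrays was 0.839 to 0.868, against 0.727 to 0.791 for the other epidermis arrays. Its 25S ribosomal RNA control signal was 1087.5, where the mean of the epidermis group was 5102 ± 2981 (SD, n = 4). The mean 3' to 5' signal ratio of the Arabidopsis control transcripts, which grows when amplified RNA is short, was 2.15 on the log2 scale in this array. Over all arrays that ratio ran from 1.52 to 2.86, with the highest value in stele replicate 2.

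**Figure D1:**
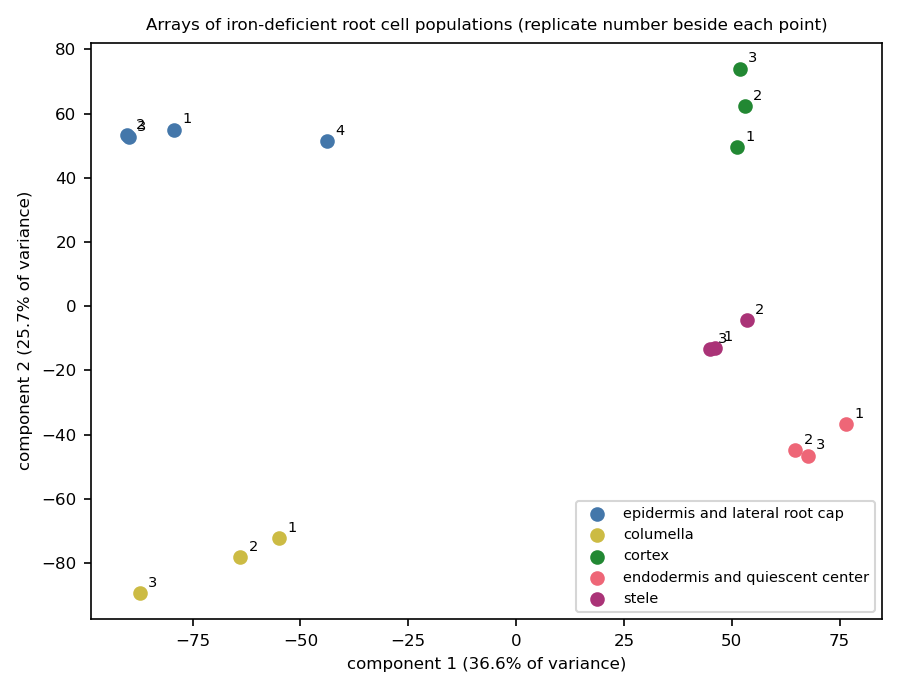
Principal components of the 16 arrays, computed on log2 signals of 16221 probe sets; each point is an array, coloured by population and marked with its replicate number. Component 1 (horizontal, 36.6% of variance) and component 2 (vertical, 25.7%) part the populations, and epidermis replicate 4, at -43.8 on component 1, sits between the other epidermis arrays (-90.2 to -79.2) and the cortex arrays (51.3 to 53.0).

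Most of the transcripts measured differed with cell identity. Of 16221 probe sets, 13326 (82.2%) differed among the 5 populations in limma's moderated F test at an adjusted p under 0.05, and 3524 (21.7%) were enriched, meaning higher in 1 population than in each of the other 4. Enriched probe sets numbered 1296 in columella, 742 in cortex, 730 in endodermis, 418 in epidermis and 338 in stele. Against the mean of the other 4 populations, 4203 probe sets were higher and 4201 lower in epidermis, 3705 and 3966 in columella, 3017 and 4582 in cortex, 3762 and 3228 in endodermis, and 2573 and 1821 in stele. In 281 of the epidermis-enriched probe sets, and in 1228, 709, 689 and 323 of those of columella, cortex, endodermis and stele, every array of the population lay above every other array. The epidermis count rests on epidermis replicate 4: without that array 1080 probe sets were epidermis-enriched, and 385 of them were among the 418. The median difference of all probe sets was not 0 under the deposited scaling: it was -0.17 (log2) in cortex, against -0.06 after quantile normalization, and 0.05 in endodermis, against -0.07. The majority in endodermis turned with it, to 3181 higher and 3979 lower, and also with the filter at the 60th percentile, to 2655 and 2913.

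Of 21 listed regulators of the iron deficiency response, the annotation named 11, and only these were tested. They were mostly lower in the epidermis, and single members had their maximum in cortex, endodermis, stele or columella. Of these 11 regulators, 9 were lower in epidermis than the mean of the other 4 populations, 1 was higher and 1 did not pass (9 and 1 also when adjusted over the list alone). The median difference was -0.91 (log2), with an adjusted p of 0.0026 for the list in camera, which compares a list with all other genes. The call was lost with an estimated correlation (adjusted p = 0.11 with an estimated correlation). BHLH101 (AT5G04150), a transcription factor of the iron deficiency response, had a signal of 27.4 ± 8.59 (SD, n = 4) in epidermis and 248.8 ± 46.3 (SD, n = 3) in cortex. In cortex 4 of the 11 regulators were higher and 2 were lower, and the list did not pass (adjusted p = 0.085; adjusted p = 0.31 with an estimated correlation), except without cortex replicate 3 (adjusted p = 0.046). The cortex-high ones were BHLH101 (3.48-fold above the mean of the other populations, adjusted p = 2.3e-06), BTSL1 (AT1G74770, a ubiquitin ligase related to BRUTUS; 3.83-fold, adjusted p = 2.8e-06), BHLH115 (AT1G51070; 2.29-fold, adjusted p = 4.9e-05) and AT3G07720, which encodes a kelch-repeat protein (7.15-fold, adjusted p = 6.2e-08). The last had a signal of 2774 ± 929.1 (SD, n = 3) in cortex against 735.2 ± 197.1 (SD, n = 3) in endodermis, the next population.

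Other regulators of that list had their maximum elsewhere. IMA1 (AT1G47400), which encodes a small peptide that acts in iron signalling, was 5.52-fold higher in stele (adjusted p = 1.4e-06), at 243.5 ± 36.5 (SD, n = 3) against 51.5 ± 17.7 (SD, n = 3) in endodermis. BTSL2 (AT1G18910), the closest relative of BTSL1, was 1.97-fold higher in columella and 3.01-fold lower in stele (adjusted p = 0.00039 and 7.6e-06), and it was the 1 regulator that was higher in epidermis (1.52-fold, adjusted p = 0.0072). The transcription factors BHLH104 (AT4G14410), ILR3 (AT5G54680), BHLH34 (AT3G23210) and BHLH121 (AT3G19860) were 1.46- to 1.76-fold higher in endodermis, with adjusted p from 0.0011 to 0.0098. BHLH121 had its maximum in columella (1.65-fold, adjusted p = 0.0045). BHLH34 was also higher in stele (1.585-fold, adjusted p = 0.0071) and in columella (1.38-fold, adjusted p = 0.032). ILR3 lost its call without endodermis replicate 1 (adjusted p = 0.062) or replicate 3 (adjusted p = 0.082). PYE (AT3G47640) was lower in epidermis (1.42-fold, adjusted p = 0.022) and did not pass elsewhere. In columella it was 1.32-fold higher (adjusted p = 0.1), and it passed there with array weights (adjusted p = 0.046) and without columella replicate 2 (adjusted p = 0.036). In columella 3 of the 11 regulators were higher and 2 lower, against 4 and 2 when adjusted over the list alone. In endodermis 4 were higher and 1 lower, in stele 2 were higher and 1 lower, and these counts were the same when adjusted over the list alone; the list passed in none of these 3 populations (adjusted p = 0.54, 0.28 and 0.49, and 0.64, 0.43 and 0.63 with an estimated correlation).

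Of 23 listed iron uptake genes, the annotation named 4, and 2 of these passed the filter and were tested. F6'H1 (AT3G13610), the feruloyl-CoA hydroxylase that makes the precursor of iron-mobilising coumarins, was 14.7-fold higher in cortex (adjusted p = 1.3e-06), with a signal of 1084 ± 80.0 (SD, n = 3). It was also higher in stele (2.38-fold, adjusted p = 0.028), at 253.1 ± 89.7 (SD, n = 3), and 8.26-fold lower in columella (adjusted p = 8.6e-06), at 15.5 ± 12.7 (SD, n = 3). BGLU42 (AT5G36890), a beta-glucosidase that acts on phenolic glucosides, was 1.56-fold higher in epidermis (adjusted p = 0.0077). The ferric reductase FRO2 and the iron transporter IRT1 were not named by the annotation and are not analysed here. Of zinc and copper transport genes, the metal transporters ZIP9 (AT4G33020) and MTP2 (AT3G61940) were 2.32- and 4.16-fold higher in epidermis (adjusted p = 0.0029 and 0.0021). Without epidermis replicate 4 the log2 difference of MTP2 went from 2.06 to 2.83.

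**Figure D2:**
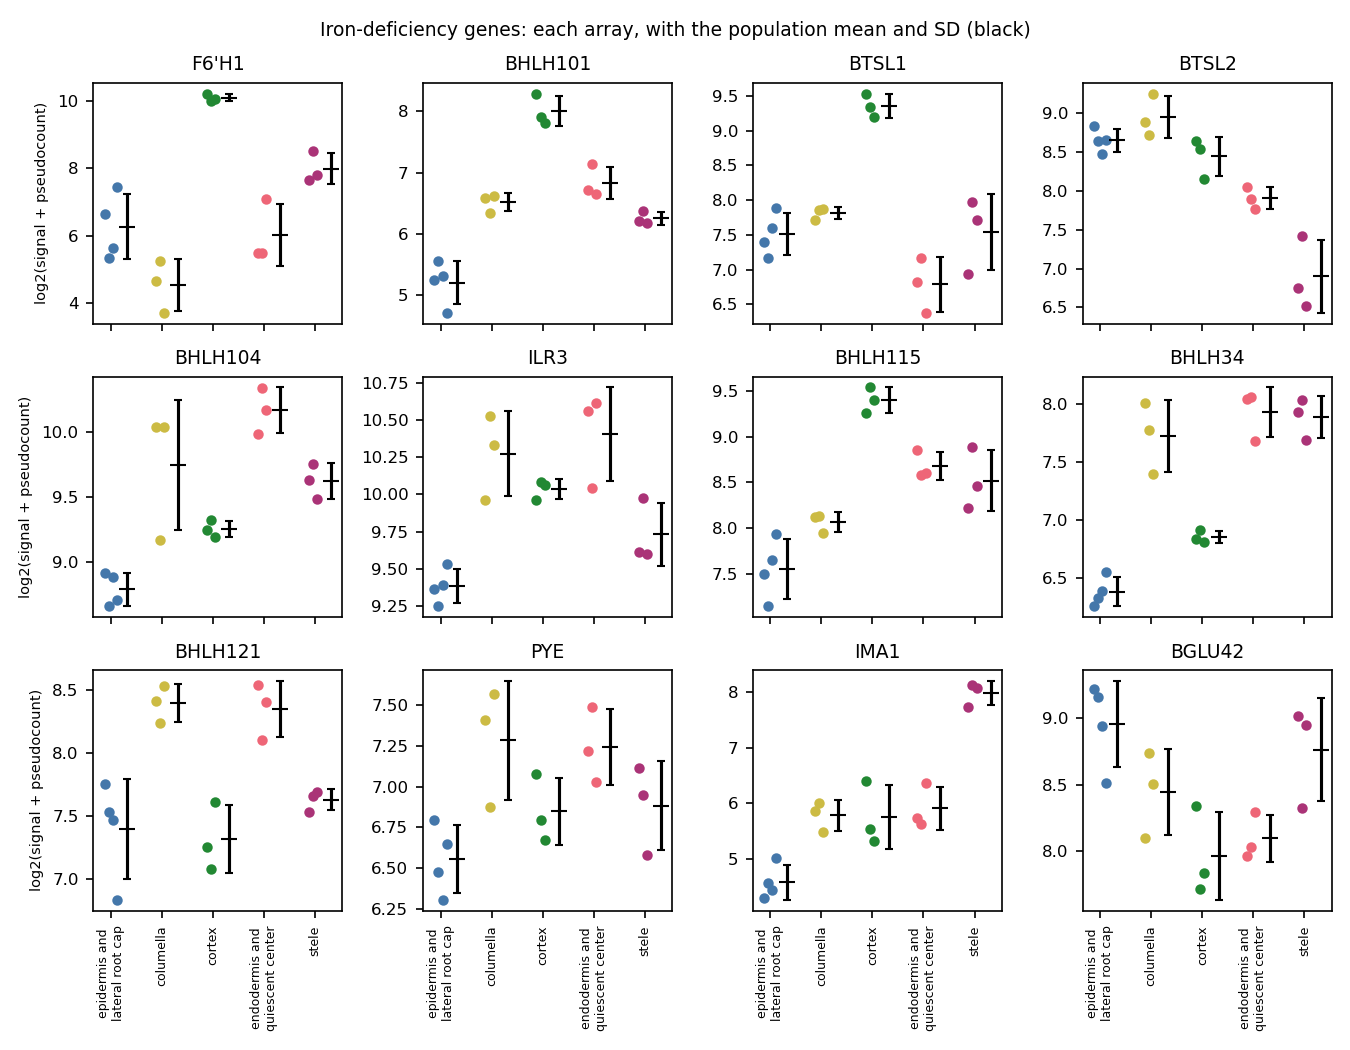
Levels of 12 genes of iron regulation and uptake in the 5 populations, as log2(signal + pseudocount) on the vertical axis; coloured points are arrays, and the black mark with its bar is the population mean and SD (n = 4 for epidermis and lateral root cap, n = 3 for each other population). F6'H1, BHLH101, BTSL1 and BHLH115 have their highest mean in cortex, IMA1 in stele, and BHLH104, ILR3 and BHLH34 in endodermis.

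In the epidermis, 418 probe sets were enriched, 25 of them with a gene symbol. GH9C3 (AT4G11050), a glycosyl hydrolase of the endoglucanase family, was 7.99-fold above endodermis, the next population (log2 difference 3.00, SE 0.48, adjusted p = 5.2e-05), at 326.6 ± 135.0 (SD, n = 4) against 35.4 ± 26.9 (SD, n = 3). The aldehyde dehydrogenase gene ALDH3F1 (AT4G36250) was 5.20-fold above its next population (adjusted p = 4.7e-06), the bHLH transcription factor gene ATMYC1 (AT4G00480) 5.17-fold, scpl18 (AT1G33540), a serine carboxypeptidase-like gene, 4.39-fold, and the flavonoid glycosyltransferase gene UF3GT (AT5G54060) 4.00-fold. The other 5 of the 10, sks16, CXE18, LSM6A, Fes1C and scpl29, were 2.16- to 3.66-fold above their next population. Among genes with a symbol whose every array in the population lay below every other array, those with the largest decrease in epidermis were LCR68 (AT2G02130), which encodes a defensin-like peptide and was 26.6-fold lower than the mean of the other populations, the subtilase gene SBT4.12 (AT5G59090; 25.4-fold), the xyloglucan-modifying enzyme gene XTH21 (AT2G18800; 17.5-fold) and ATC (AT2G27550; 16.2-fold), with adjusted p of 3.8e-07 or less. Among epidermal markers, TRY (AT5G53200), a regulator of epidermal hair patterning, was 2.06-fold higher (adjusted p = 0.0066). It was the 1 tested gene of 11 listed for patterning, and 3 of 20 root hair genes were tested. The root hair expansin genes EXPA7 (AT1G12560) and EXPA18 (AT1G62980) were 2.59- and 1.92-fold higher (adjusted p = 0.029 and 0.024), but the signal of EXPA7 was 386.3 ± 321.9 (SD, n = 3) in cortex against 335.2 ± 129.8 (SD, n = 4) in epidermis. Both lost the call without epidermis replicate 1 (adjusted p = 0.11 and 0.13) or replicate 2 (0.072 and 0.056), and EXPA7 also without a pseudocount (adjusted p = 0.053). The remaining root hair gene, SCN1, did not pass in epidermis (1.32-fold, adjusted p = 0.082) and was highest in stele. CXE18 lost its call without endodermis replicate 1 (adjusted p = 0.09) and with the replicate number as a block (adjusted p = 0.057), ATMYC1 went from a log2 difference of 2.37 to 1.65 without cortex replicate 1, and LCR68 from -4.74 to -5.37 without epidermis replicate 4.

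In the columella, the gravity-sensing core of the root cap, single genes of starch metabolism and auxin response were far above the other populations. JRG21 (AT3G55970), a jasmonate-regulated oxygenase gene, was 23.8-fold above epidermis (log2 difference 4.58, SE 0.39, adjusted p = 1.6e-07), at 2029 ± 472.2 (SD, n = 3). IAA20 (AT2G46990) and IAA33 (AT5G57420), members of the Aux/IAA family of auxin response repressors, were 10.5- and 9.22-fold above their next populations. The glutathione transferase gene GSTU20, the endoglucanase gene GH9B6 and the expansin gene EXPA4 were 9.16- to 9.69-fold higher than in epidermis. PWD (AT5G26570), which phosphorylates starch, PPDK (AT4G15530), pyruvate orthophosphate dikinase, APL4 (AT2G21590), a subunit of ADP-glucose pyrophosphorylase, and KICP-02 were 7.26- to 8.66-fold above epidermis. Of the starch list, 4 members were tested, and 3 (APL4, DPE1 and SBE2.2) were higher in columella, by 5.34- to 13.7-fold against the mean of the other populations, as they were when adjusted over the list alone. APL3 was 1.45-fold higher and did not pass (adjusted p = 0.22). The list passed in camera in columella (adjusted p = 0.0037, higher) and in endodermis, where all 4 were lower (adjusted p = 0.012; all 4 also when adjusted over the list alone), and neither call was kept with an estimated correlation (adjusted p = 0.11 and 0.13 with an estimated correlation). In cortex 3 of the 4 were lower and in stele 2, in epidermis 1 was higher, and the list did not pass there (adjusted p = 0.16, 0.16 and 0.46); these counts were the same when adjusted over the list alone.

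Of the root cap list, 2 genes were tested. RCPG (AT1G65570), a root cap polygalacturonase, was 29.4-fold higher in columella (adjusted p = 4.3e-07), at 7529 ± 532.5 (SD, n = 3), and 4.78-fold higher in epidermis with lateral root cap (adjusted p = 0.00048), at 2012 ± 1232 (SD, n = 4). PASPA3 (AT4G04460), an aspartic protease gene of cells that undergo developmental cell death, was higher in epidermis (2.71-fold, adjusted p = 0.00029) and in stele (3.88-fold, adjusted p = 9.3e-05), and did not pass in columella (1.22-fold, adjusted p = 0.47). Of 5 auxin response genes tested, all 5 were lower in epidermis (adjusted p = 0.0087 for the list, 0.11 with an estimated correlation; all 5 also when adjusted over the list alone). In columella IAA20, IAA30 (AT3G62100) and GH3.5 (AT4G27260) were 5.45- to 16.9-fold higher, while GH3.3 (AT2G23170), an enzyme gene of auxin conjugation like GH3.5, was 5.84-fold lower there and 5.81-fold higher in cortex. The counts were 3 higher and 1 lower in columella, 1 and 4 in cortex, and 1 and 0 in stele, all unchanged when adjusted over the list alone, and 0 and 1 in endodermis (0 and 0 when adjusted over the list alone). The list did not pass in these populations (adjusted p = 0.16, 0.28, 0.15 and 0.98), and its direction in endodermis was not stable. By the same rule as in epidermis, the largest decreases in columella were those of GAT1_2.1 (AT1G15040), a glutamine amidotransferase-like gene (13.6-fold), the plastid gene psbZ of photosystem II (log2 difference -3.46), the transcription factor gene BZIP61 (AT3G58120; -3.46) and TBL41 (10.7-fold), with adjusted p of 1.1e-07 or less.

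In the cortex, 742 probe sets were enriched, and the 4 markers of the cortex that could be tested were high. PMEPCRF (AT5G53370), a pectin methylesterase gene, was 9.97-fold above stele (log2 difference 3.32, SE 0.35, adjusted p = 3.5e-06), at 2639 ± 526.9 (SD, n = 3). The glucosyltransferase genes UGT84A1 (AT4G15480), whose product acts on hydroxycinnamic acids, and UGT76B1 (AT3G11340) were 9.54- and 6.07-fold above endodermis, and the cytochrome P450 gene CYP71B34 (AT3G26300) was 8.97-fold above it. Of the 10 genes taken by rule, 4 encode proteins of the chloroplast's photosynthetic machinery: ATPC1 (AT4G04640), a subunit of ATP synthase (7.38-fold), the Rubisco activase gene RCA (AT2G39730; 6.19-fold), NdhS (AT4G23890), a subunit of the NADH dehydrogenase-like complex (5.86-fold), and the photosystem I gene PSAN (AT5G64040; 5.35-fold), each against the next population and with adjusted p of 3.5e-05 or less. The AP2-type transcription factor gene tny and TBL41 were 5.39- and 5.37-fold above stele. The rule took only genes with a symbol, which 70 of the 742 cortex-enriched probe sets had. Genes listed by a locus tag alone differed more, such as AT2G03370 (11.75-fold above endodermis) and AT3G18170 (8.89-fold). The 4 photosynthetic genes therefore do not describe the cortex-enriched probe sets at large. PSAN was the 1 member of the photosynthesis list that the annotation named among those tested. All 4 cortex markers tested were higher in cortex, by 3.51- to 22.8-fold (all 4 also when adjusted over the list alone), and the list passed (adjusted p = 3.9e-05), a call not kept at an adjusted p = 0.05 with an estimated correlation. Among them were AT1G62510, at 2359 ± 573.4 (SD, n = 3) in cortex and 289.5 ± 122.6 (SD, n = 3) in endodermis, and AT1G09750, at 835.6 ± 497.1 (SD, n = 3) and 56.9 ± 11.9 (SD, n = 3). AT1G09750 is also the 1 gene of the reporter list that could be tested. Its level in cortex may follow from the sort itself and is no independent check. It still counts among the 4 markers and in the list test.

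The same 4 markers were lower in columella (4 of 4, adjusted p = 0.012, and 0.13 with an estimated correlation). In epidermis 1 was higher and 3 lower, in stele 1 was lower and in endodermis none passed, and the list did not pass in these populations (adjusted p = 0.28, 0.14 and 0.54); all 4 counts were the same when adjusted over the list alone. Among epidermis arrays, replicate 4 had the highest signals of these markers, such as 253.4 for AT1G62510 against 50.1 to 66.6 in replicates 1 to 3. The genes named by that rule as reduced in cortex were JRG21 (6.93-fold), scpl20 (6.15-fold), PHV (AT1G30490), a class III homeodomain gene (5.47-fold), and the chaperone gene Hsp70-2 (5.32-fold), with adjusted p of 5e-06 or less. Of 16 genes listed for mitosis and 14 for DNA replication, only 2 and 1 were tested, and the lists as such were not. The Aurora kinase genes AUR1 (AT4G32830) and AUR2 (AT2G25880) were 2.80- and 4.44-fold lower in cortex (adjusted p = 0.00046 and 3e-06), and PRL (AT4G02060), a replication licensing factor, was 2.68-fold lower (adjusted p = 0.0013). The counts for cortex depend on single arrays. Without cortex replicate 3, 2915 probe sets were lower in cortex, where all arrays gave 4582. Without replicate 2 there were 3401, and without replicate 1 there were 4532.

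**Figure D3:**
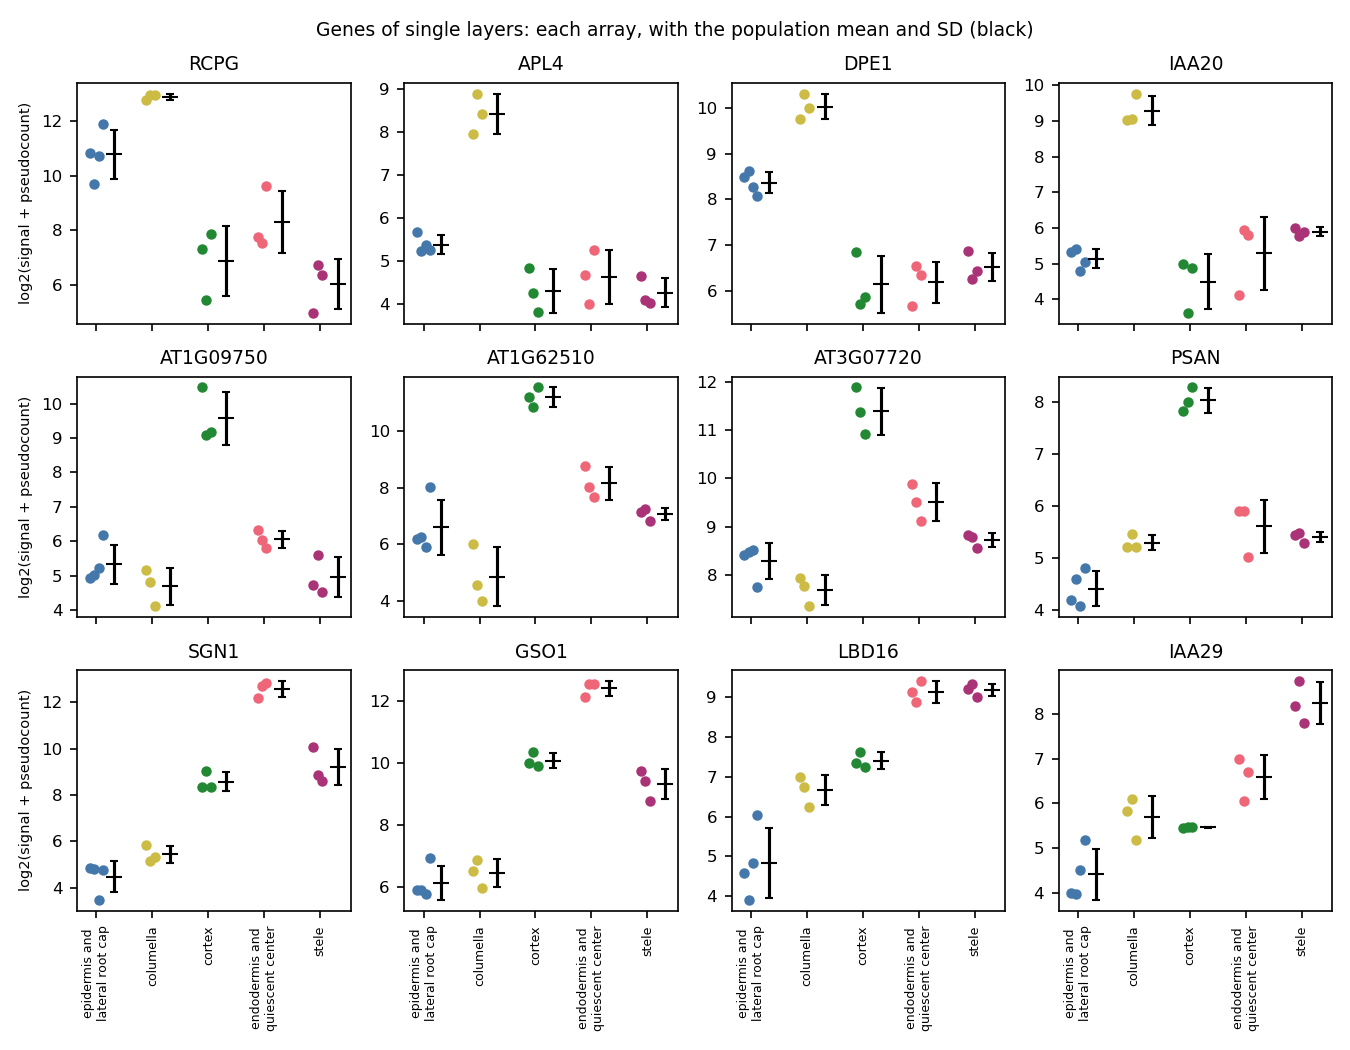
Levels of 12 genes with a maximum in a single population or in adjoining ones, as log2(signal + pseudocount) on the vertical axis; coloured points are arrays, and the black mark with its bar is the population mean and SD (n = 4 for epidermis and lateral root cap, n = 3 for each other population). RCPG, APL4, DPE1 and IAA20 are highest in columella, AT1G09750, AT1G62510, AT3G07720 and PSAN in cortex, SGN1 and GSO1 in endodermis, LBD16 in endodermis and stele, and IAA29 in stele.

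In the endodermis, the 2 tested members of the list for the Casparian strip, the lignin barrier between endodermal cells, were high. SGN1 (AT1G61590), a kinase gene, and GSO1 (AT4G20140), a receptor kinase gene, both needed for a closed strip, were 50.6- and 21.4-fold above the mean of the other populations (adjusted p = 1e-09 and 1.1e-09). Signals in endodermis were 6265 ± 1378 and 5445 ± 864.4 (SD, n = 3), and in epidermis 13.7 ± 8.51 and 63.3 ± 31.8 (SD, n = 4). CCR2 (AT1G80820), a cinnamoyl-CoA reductase gene of lignin-type phenolics, was 11.7-fold above stele, the largest difference among the endodermis genes with a symbol named by rule (log2 difference 3.55, SE 0.35, adjusted p = 4.6e-06). TBL30 (AT2G40160) was 7.54-fold above stele, the plant defensin gene PDF2.5 (AT5G63660) 7.23-fold, the receptor kinase gene B120 (AT4G21390) 6.68-fold, TRM21 6.64-fold and TRI 6.03-fold. The other 4 of the 10 were encoded in the plastid: atpH, atpI, rpl36 and rps14, 6.00- to 7.28-fold above cortex, the next population. Only 76 of the 730 endodermis-enriched probe sets had a symbol. Genes listed by a locus tag alone differed more, such as AT2G21100 (18.92-fold above stele), so these 10 do not describe the enriched probe sets at large. The endodermis arrays also had the highest hybridization spike-in signals, at 11.06 ± 0.13 (mean log2, SD, n = 3) against 9.42 to 10.35 in all other arrays. The genes named as reduced in endodermis by that rule were CYP71B6 (8.54-fold), NAI1 (AT2G22770; 6.24-fold), BGLU25 (6.23-fold) and NAI2 (AT3G15950; 6.17-fold), with adjusted p of 4.1e-06 or less. NAI1 and NAI2 are needed for the endoplasmic reticulum bodies that store beta-glucosidases.

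Further members of the gene lists were high in endodermis. HCT (AT5G48930) and COSY (AT1G28680), enzyme genes of phenylpropanoid and coumarin synthesis, were 4.67- and 2.48-fold higher (adjusted p = 6.2e-07 and 1.6e-05), and both were also higher in stele. COSY was also higher in cortex (1.92-fold, adjusted p = 0.00036). F6'H1, the third tested member of the phenylpropanoid list, was 2.29-fold lower in endodermis (adjusted p = 0.024). AGL42 (AT5G62165) and BBM (AT5G17430), genes of the stem cell niche, were 3.66- and 2.46-fold higher (adjusted p = 1.6e-05 and 0.0057), and BBM did not pass without endodermis replicate 2 (adjusted p = 0.088). AUR2 and PRL were 2.60- and 1.93-fold higher (adjusted p = 0.00022 and 0.02), and PRL did not pass without endodermis replicate 2 (adjusted p = 0.11) or replicate 3 (adjusted p = 0.085). The flavonoid gene DFR (AT5G42800) was 1.77-fold higher (adjusted p = 0.014; 0.077 without endodermis replicate 1), while CHIL (AT5G05270), of the same list, was 3.04-fold higher in cortex (adjusted p = 0.00018). The suberin gene FACT (AT5G63560) was 1.92-fold higher (adjusted p = 0.0053) under the deposited scaling but did not pass after quantile normalization (log2 difference 0.53, adjusted p = 0.11).

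In the stele, 338 probe sets were enriched. TBL36 (AT3G54260), of a family that acetylates wall polysaccharides, was 7.19-fold above columella (log2 difference 2.85, SE 0.48, adjusted p = 0.00014), at 1600 ± 349.3 (SD, n = 3). The calmodulin-binding protein gene iqd33 (AT5G35670) was 6.39-fold above epidermis, SAH7 (AT4G08685) 5.63-fold above endodermis, the subtilase gene SBTI1.1 (AT1G01900) 5.41-fold above columella, scpl35 5.40-fold and the methionine gamma-lyase gene MGL (AT1G64660) 5.03-fold above endodermis, and NDB3, an NAD(P)H dehydrogenase gene, 5.01-fold above cortex. IAA31 (AT3G17600), the protein kinase gene PID2 (AT2G26700) and the actin gene ACT11 (AT3G12110) were 3.52- to 4.23-fold above their next populations. Among members of the gene lists, IAA29 (AT4G32280) was 6.52-fold higher (adjusted p = 2.1e-06). The lateral root regulator LBD16 (AT2G42430) was 4.51-fold higher in stele and 4.34-fold in endodermis (adjusted p = 2.9e-05 and 2.5e-05), as was the sugar transporter gene SWEET11 (AT3G48740) at 3.95- and 4.31-fold. LHW (AT2G27230), a regulator of vascular cell number, was 1.99-fold higher (adjusted p = 0.0028) and AUR1 3.15-fold (adjusted p = 0.00028). LBD29 (AT3G58190) was 2.45-fold higher (adjusted p = 0.023) but did not pass without stele replicate 1, 2 or 3 (adjusted p = 0.078, 0.074 and 0.084) or without a pseudocount (adjusted p = 0.058). The rule for decreases named EXO (AT4G08950; 5.69-fold), UGT85A2 (5.07-fold), ENGase85A (4.75-fold) and IQD22 (3.96-fold), with adjusted p of 2.9e-06 or less. Without stele replicate 3 the counts were 1702 higher and 1197 lower, where all arrays gave 2573 and 1821.

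Genes of stress that can respond to protoplasting differed between populations. The heat shock gene HSP17.6C (AT1G53540) was 4.69-fold higher in columella (adjusted p = 4.9e-06), and HSP22.0 (AT4G10250) was highest in endodermis without passing there (1.72-fold, adjusted p = 0.077). HSP22.0 passed in endodermis with array weights (adjusted p = 0.012), without epidermis replicate 4 (0.041) and without cortex replicate 1 (0.015). The wound-responsive regulator gene ZAT10 (AT1G27730) was 2.36-fold higher in columella (adjusted p = 0.00021), at 5225 ± 929.8 (SD, n = 3). WRKY53 (AT4G23810) was 1.68-fold higher in epidermis (adjusted p = 0.016), a call that was lost without epidermis replicate 4 (adjusted p = 0.089) and with the replicate number as a block (adjusted p = 0.077). The cytokinin response gene ARR15 (AT1G74890) was 1.71-fold higher in columella (adjusted p = 0.022) but did not pass without columella replicate 2 (adjusted p = 0.13) or replicate 3 (adjusted p = 0.064). UGT74B1 (AT1G24100), an enzyme of glucosinolate synthesis, was 1.99-fold lower in epidermis (adjusted p = 6.7e-05), and SCN1 (AT3G07880), of the root hair list, was highest in stele (2.62-fold, adjusted p = 7.7e-05).

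Along the radial axis, which runs from epidermis through cortex and endodermis to stele, 3323 probe sets rose inward and 2459 fell at an adjusted p under 0.05 for the slope per layer. Such a slope does not require a change at every layer, since a difference in 1 layer alone can give it. After quantile normalization the majority turned, with 2941 rising and 3058 falling. Among genes with a symbol, the steepest rises were those of SBT4.12 (4.04-fold per layer, log2 slope 2.02, SE 0.13, adjusted p = 2e-09), LCR68 (4.02-fold), XTH21 (3.95-fold), SBTI1.1 (3.46-fold) and LCR69 (AT2G02100; 3.38-fold). SBT4.12, LCR68 and XTH21 were also among the genes named for the largest decreases in epidermis. SBT4.12 had signals of 62.4 ± 43.0 (SD, n = 4) in epidermis, 636.6 ± 190.7 in cortex, 3076 ± 481.0 in endodermis and 3923 ± 731.4 in stele (SD, n = 3 each). The steepest falls among them were those of sks16, a gene related to multicopper oxidases (log2 slope -1.55), GH3.17 (AT1G28130), which encodes an enzyme that conjugates auxin (-1.47), sks15 (-1.43), the copper amine oxidase gene CuAO1 (-1.42) and hemb2 (AT1G44318), a gene of porphyrin synthesis (-1.38), with adjusted p of 1.3e-07 or less. GH3.17 had 1661 ± 523.8 (SD, n = 4) in epidermis, 1081 ± 34.1 (SD, n = 3) in cortex and 101.5 ± 22.7 (SD, n = 3) in stele. In columella, which is not part of the slope, it had 6184 ± 1310 (SD, n = 3).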

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

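The tests on epidermis replicate 4 and on plastid transcripts in this part were chosen after the values had been seen, while the regroupings of the arrays were set before their results. A first test of replicate 4, on the median of all probe sets enriched in each other population (0.46 for cortex, 0.24 for endodermis, 0.06 for stele, 0.04 for columella, log2), was replaced because transcripts that are abundant in epidermis too hide a small share of other cells. The stele was added to the explanation after its share was seen, and the bound for nuclear photosynthesis genes in endodermis was reworded after its value was seen, which turned the outcome of that test from open to argued against.

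Epidermis replicate 4 lay apart from replicates 1 to 3, and without it 1080 probe sets were epidermis-enriched where all arrays gave 418; an even admixture of all other cell types is argued against, since the shares of abundant transcripts of cortex and columella lay 5.31 percentage points apart. Cells of cortex and stele in this sort may account for part of the difference: over 59 transcripts abundant in cortex the median share in replicate 4 was 6.28% of the cortex signal (5.14 to 8.42), above each of replicates 1 to 3 in 51 of them, and over 33 stele transcripts it was 5.21% (4.17 to 6.28), above each in 32. The excess is not confined to these layers, since 101 endodermis transcripts had a share of 1.07% (0.63 to 1.58), where replicates 1 to 3 reached at most 0.45%. The transcripts of each layer were chosen for a mean signal there over 1000 and over 10 times that of epidermis replicates 1 to 3. Replicate 4 took no part in that choice, which tilts each share toward an excess in it. Brackets hold 95% bootstrap intervals over transcripts of 1 array, with no spread between arrays. Shorter transcripts stay open too, since the 3' to 5' ratio lay 0.412 (log2) above the highest of replicates 1 to 3, which spanned 0.21. AT3G07720, which is high in cortex, was lower in replicate 4 (7.74 against 8.41 to 8.52, log2), RCPG and PASPA3 of the root cap were higher (3737 against 817 to 1802, and 3401 against 725.1 to 1244), and no biological explanation was tested because the labels name no difference between the replicates.

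Among 127 named genes, 16 had an epidermis array farther from the others than Dixon's 95% critical value allows, 11 of them replicate 4, while 0 of 6 quality measures did. Chance gives such a value in about 1 of 20 groups. In replicate 4 the log2 level was 6.853 for rps14 (5.29 to 5.34 in the others), 8.03 for SAH7 (5.61 to 5.97), 5.116 for SBTI1.1 (3.53 to 3.73), 8.245 for ENGase85A (9.09 to 9.19) and 7.742 for AT3G07720. It was 8.042 for AT1G62510 (5.91 to 6.26), 6.918 for GSO1 (5.76 to 5.91), 4.728 for BBM (5.44 to 5.51), 9.434 for WRKY53 (8.10 to 8.28), 5.194 for HSP22.0 (4.07 to 4.24) and 8.844 for UGT74B1 (8.10 to 8.12). In replicate 3 it was 4.646 for DFR (5.06 to 5.09), 9.789 for SCN1 (10.05 to 10.09) and 3.482 for SGN1 (4.77 to 4.84). In replicate 2 it was 7.866 for BZIP61 (8.12 to 8.17) and 5.636 for AT5G02000 (6.64 to 6.79).

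Outside the genes compared, the control probe set for sequence U12639 had a mean signal of 7129 ± 1494 (SD, n = 3) in columella and 0.886 to 28.9 in all other arrays.

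Transcripts encoded in the plastid were high in endodermis and cortex and low in columella, with medians over 69 probe sets of 2.07, 0.94 and -2.14 (log2). Less RNA on the array is argued against for cortex and columella, whose spike-ins differed by -0.309 (cortex minus columella, log2), but cannot be told apart for endodermis, where every array lay at least 0.565 above all others. A photosynthesis programme that raises nuclear genes as much as plastid ones is, by the reworded bound, argued against in endodermis, where the median of 13 nuclear genes was -0.178 (-0.29 to 0.28; 0.022 without a pseudocount and 0.002 without endodermis replicate 3) and the plastid interval was 1.92 to 2.25. These are 95% bootstrap intervals over probe sets. Probe sets vary together (estimated correlation 0.551 for the plastid set), and the intervals hold no spread between arrays, so they understate the uncertainty. In cortex the nuclear median was 2.334 (2.06 to 2.85), above the plastid interval of 0.76 to 1.20. A photosynthesis programme may hold there, but the nuclear genes were raised more than the plastid ones. Moreover, 4 of the 13 genes had already been seen among the cortex genes named by rule. Priming of organelle transcripts may contribute as well, since mitochondrial transcripts had medians of 1.47 in endodermis, 0.848 in cortex and -1.75 in columella (log2), and differences between the cell types themselves stay open.

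Chance assignment of arrays to populations was argued against for each count: among 100 assignments, the real one included, only 1, the real one, gave as many probe sets. Since arrays of 1 population resembled each other, this outcome was likely in advance. It does not part cell identity from other differences between populations, such as the reporter line or the sort. The F test gave 13326 against at most 1654 in the other assignments. Against the other 4 populations, epidermis gave 8404 against 872, columella 7671 against 3500, cortex 7599 against 483, endodermis 6990 against 2021 and stele 4394 against 2701. Enriched probe sets numbered 418 against 0, 1296 against 664, 742 against 0, 730 against 194 and 338 against 5 in the same order, and the radial slope gave 5782 against 2201.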

How the results depend on the processing

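Of 137 values of named genes, 134 passed, and 124 kept direction and call in all settings that tested them (123 of the 137 with the filter at the 60th percentile) and without each array. Genes taken by rule had to pass and had the largest differences. Members of the gene lists entered in the population of their highest mean. These numbers therefore do not describe genes at large. Counts stayed within 1.5 times under each alternative except those given here. The alternatives were planned, except those on organelle genes and families, and the cause of a change was not tested unless given. The F test gave 10557 to 14552 probe sets. Epidermis-enriched probe sets (418) became 1215 with array weights (410 shared), 1017 with a replicate block (382 shared), and 279 to 1080 leaving out arrays (1080 without epidermis replicate 4, 385 shared). Replicate 4 is alone in its number, so the block absorbs it by construction. The residuals gave no sign that replicate numbers pair the samples. Those of arrays with the same number had a median r of 0 (-0.26 to 0.24), as had those with different numbers (-0.37 to 0.36). The labels do not say what the numbers mean, so a pairing is not excluded. Probe sets lower in cortex (4582) ran from 2915 (without cortex replicate 3) to 5085, those higher in stele (2573) from 1702 (without stele replicate 3) to 2906 and those lower (1821) from 1197 (without stele replicate 3) to 2061. Calls of gene lists (6) became 0 with an estimated correlation, 15 with fry and 2 with the filter at the 60th percentile, where starch and cortex markers had under 4 members, and iron regulators passed in cortex without cortex replicate 3. The auxin response list in endodermis, which did not pass (mean 0.075), turned its test direction with quantile normalization (-0.098), a 40th percentile pseudocount (-0.046) and no filter (0.075), and without 8 of the arrays (means of -0.026, 0.044, 0.047, 0.05, 0.07 and 0.09, in a range of -0.026 to 0.182 over all left-out arrays). Under quantile normalization the median of all probe sets moved by 0.11 (log2) in cortex and -0.12 in endodermis, and the share of calls that were higher in endodermis fell from 53.8 to 44.4%, and that of slopes rising inward from 57.5 to 49.0%. Signal over background limits genes near the pseudocount, such as LBD29 and MTP2.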

Other observations

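The families and organelle sets in this part were chosen after the data had been seen, and none of their 7 calls among 150 pairs was kept with an estimated correlation. In cortex, 18 of 35 tested genes of the UGT family of glycosyltransferases, which attach sugars to small molecules, were higher and 7 were lower (median 0.63, log2; adjusted p = 0.0019 in camera; adjusted p = 0.73 with an estimated correlation). Of 8 ATG genes of autophagy, 7 were lower and 1 was higher in epidermis (median -0.98; adjusted p = 0.042; adjusted p = 0.84 with an estimated correlation). All of them were ATG8 genes except ATG3, so the counts do not describe autophagy genes at large. Of 7 IAA genes, repressors of the auxin response that in part belong to the auxin list, 6 were lower in epidermis and 0 higher (median -1.15; adjusted p = 0.016; adjusted p = 0.73 with an estimated correlation).

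All 69 plastid-encoded probe sets were lower in columella (median -2.14, adjusted p = 6.6e-25) and 42 were lower in epidermis (-0.81, adjusted p = 4.9e-05), while 65 were higher in endodermis (2.07, adjusted p = 2.4e-24) and 43 in cortex (0.94, adjusted p = 1.1e-12). With an estimated correlation the adjusted p was 0.73 to 0.84. Of 13 mitochondrion-encoded probe sets, 12 were lower in columella (-1.75), 12 were higher in endodermis (1.47) and 11 in cortex (0.85). Of 13 nuclear genes of photosynthesis, 10 were higher in cortex (2.33), 10 were lower in epidermis (-1.26) and 3 were higher in endodermis, where the median was -0.18 and the mean 0.04. Over all alternatives, left-out arrays included, each median in this part kept its sign, except that of the nuclear genes in endodermis, which was 0.022 without a pseudocount and 0.002 without endodermis replicate 3.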
